A study of Papio anubis with 60 samples.

How the data were processed

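Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map 4 histone marks in pluripotent cells of the olive baboon, Papio anubis. Embryonic stem cells (ESC) of lines B4 and B15 and induced pluripotent stem cells (iPSC, made by reprogramming somatic cells) of lines 160-2 and M14939#3 were grown on feeder cells, per the labels' protocols. Each library came from 50000 cells whose chromatin was cut with micrococcal nuclease, and antibodies against H3K4me3, H3K27ac, H3K27me3 and H3K9me3 were used. The labels give 60 libraries in 10 groups, a group being a cell type with a mark or an input, and each group holds 3 replicates of each of 2 lines. Of the 60 libraries, 12 are inputs.

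The values used here are 8 peak lists, 1 for each cell type and mark. Per the submitters' processing notes, MACS2, SAMtools 1.10, Picard and deepTools were used. The aligner, the genome build, the calling thresholds and the way in which the libraries and inputs of a cell type were combined are not given in the sources used here. The lists of H3K4me3 and H3K27ac have the narrow layout of MACS2 and those of H3K27me3 and H3K9me3 the broad one. Each deposited list gives a fold enrichment over background for every peak, a ratio made by the authors' peak caller. Each deposited list also gives the −log10 of the p and of the q of every peak. The lowest deposited −log10 q was 1.30 in the narrow lists and 1.00 in the broad lists. Fold and −log10 q are the authors' values of single peaks, and were used here only to describe, rank or filter peaks within a list. No read counts were used, so the depth of the libraries behind a list is unknown. The 8 columns of −log10 p, 1 per list, were not used.

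Peaks of a list that overlapped were merged to regions. The share of regions in common was the percent of the regions of one list that shared at least 1 bp with a region of the other, with a 95% Wilson interval. Its chance level came from 100 circular shifts of the other list along each chromosome; those for the X, the autosomes and the H3K27me3 regions off H3K9me3 were added after the data were examined. The covered base pairs in common were also divided by those covered in either list (the Jaccard index, in percent). Firm peaks had a −log10 q of at least 5 in the narrow lists and at least 2 in the broad ones, and the stricter limits were 10 and 3. Chromosome lengths were taken as the furthest end of any peak in the 8 lists.

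The build of the lists is not given in the sources used here, and no genome sequence was used. The gene table that was at hand describes the assembly Panubis1.0, and for 12 of 21 chromosomes its furthest gene end lay over 5 Mb from the furthest peak end under the same chromosome number. The lists were therefore not joined to genes. Results planned before the data were examined for promoters, for fixed gene lists, for the rule that names the genes with the highest fold enrichment among those marked in one cell type, and for zinc finger genes were not run, and no gene is named. Domains of H3K4me3 took the place of promoters: firm H3K4me3 peaks of both cell types were joined within 1 kb, and domains of at least 2 kb were kept. The 2 kb limit was set after the numbers of domains at several limits had been seen. A domain bore a mark where a firm peak of that mark overlapped it, and it is called bivalent where firm H3K4me3 and firm H3K27me3 peaks of the same cell type overlapped it. Domain states were compared by the percent of domains in the same state and by Cohen's kappa.

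For broad H3K4me3 domains, the peaks of a cell type were joined within 1 kb and the 500 widest kept. Distal H3K27ac regions lay over 1 kb from any H3K4me3 domain; the firm ones were joined within 12.5 kb and the 500 clusters with the most covered base pairs were kept. Domains of H3K27me3 and H3K9me3 were joined within 3 kb, and a domain was called one-sided where the other cell type's list had no peak of that mark in it. Coverage was also counted in bins of 1 Mb. Autosomal bins in which H3K9me3 coverage differed by at least 20 percentage points between the cell types were joined to blocks, a measure chosen after the data were examined. Also chosen after the data were examined were the groups of peaks by −log10 q, the bins along the X, the use of H3K4me3 domains and the overlap of marks with each other. The shares in common, the choice of the widest domains (then to be compared by their genes, here by overlap), the coverage of the X and the one-sided domains were fixed before the data were examined. So were the clusters of distal H3K27ac, except that their distance was then to be taken from start sites and was set to H3K4me3 domains afterwards.

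With 1 list per cell type and mark there are no replicates of a list. No p-value was computed, no library could be left out, and differences between the lists cannot be set against the spread between lines or cultures. Intervals cover counting error only, and neighbouring regions are not independent. The SD over the 20 autosomes is given as a spread within 1 list. Positions are 1-based in the authors' coordinates and chromosome numbering. The interval functions were tested on simulated peaks, where 6 of 6 known measures were recovered from 13000 simulated peaks. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.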

Results

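The series examined H3K4me3, H3K27ac, H3K27me3 and H3K9me3 in baboon ESC and iPSC, and the comparison it implies is that of the 2 cell types for each mark. H3K4me3 marks active and poised promoters, H3K27ac active promoters and enhancers, H3K27me3 regions held by Polycomb complexes, and H3K9me3 constitutive heterochromatin and silenced repeats. Each cell type was represented by 2 lines with 3 replicates of each mark, and 1 peak list per cell type and mark was analysed. There are no replicates of a list, so every difference below is a difference between 2 lists. Cell type and cell line also cannot be separated, since each line belongs to 1 cell type.

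The H3K4me3 lists of both cell types were of similar size, and the other 3 marks differed in number. H3K4me3 had 336658 peaks in ESC and 330423 in iPSC, covering 146 Mb and 149 Mb. H3K27ac had 387478 peaks (106 Mb) in ESC and 221803 (56.5 Mb) in iPSC. H3K27me3 had fewer peaks in ESC, 80633 (81.8 Mb) against 158859 (110 Mb) in iPSC. H3K9me3 had 349276 peaks (316 Mb) in ESC and 251833 (225 Mb) in iPSC. Median widths were 272 and 287 bp for H3K4me3, 216 and 206 bp for H3K27ac, 479 and 454 bp for H3K27me3, and 552 and 532 bp for H3K9me3 in ESC and iPSC. The median fold enrichment of a peak, the authors' value, lay between 2.59 and 3.58 in the 8 lists. The number of peaks that passes a caller's threshold depends on depth, which is unknown here.

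By the Jaccard index of covered sequence, H3K4me3 was the mark with the largest part in common and H3K27me3 the one with the smallest. Of the ESC H3K4me3 regions, 69.3% overlapped an iPSC region (95% Wilson interval 69.2 to 69.5), against 10.4% in shifted lists, and 69.8% of the iPSC regions overlapped an ESC region (69.6 to 70.0). The Jaccard index was 57.3%. For H3K9me3, 56.5% of ESC regions (56.3 to 56.7) and 81.9% of iPSC regions (81.8 to 82.1) overlapped the other list, with 16.9% and 23.6% in shifted lists and a Jaccard index of 46.7%. For H3K27ac the shares were 41.9% in ESC (41.8 to 42.1) and 74.9% in iPSC (74.7 to 75.0), with 4.45% and 7.76% in shifted lists and a Jaccard index of 33.4%. For H3K27me3 they were 27.2% (26.9 to 27.5) and 16.3% (16.1 to 16.5), with 8.29% and 4.44% in shifted lists and a Jaccard index of 16.2%. The asymmetries changed when the longer list was cut by −log10 q to the number of peaks of the shorter. The shares were then 53.7% and 55.6% for H3K27ac, 66.7% and 71.2% for H3K9me3, and 17.8% and 19.7% for H3K27me3, where the order turned. This cut removes the weakest peaks, so list length and peak strength were not separated. Without the X, the ESC and iPSC shares were 64.4% and 81.4% for H3K9me3 and 38.6% and 16.1% for H3K27me3. Among the H3K27me3 regions that touched no H3K9me3 region, a subset chosen after the data were examined, 22.7% in ESC and 51.2% in iPSC overlapped the other list, with 6.74% and 4.50% in shifted lists.

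**Figure D1:**
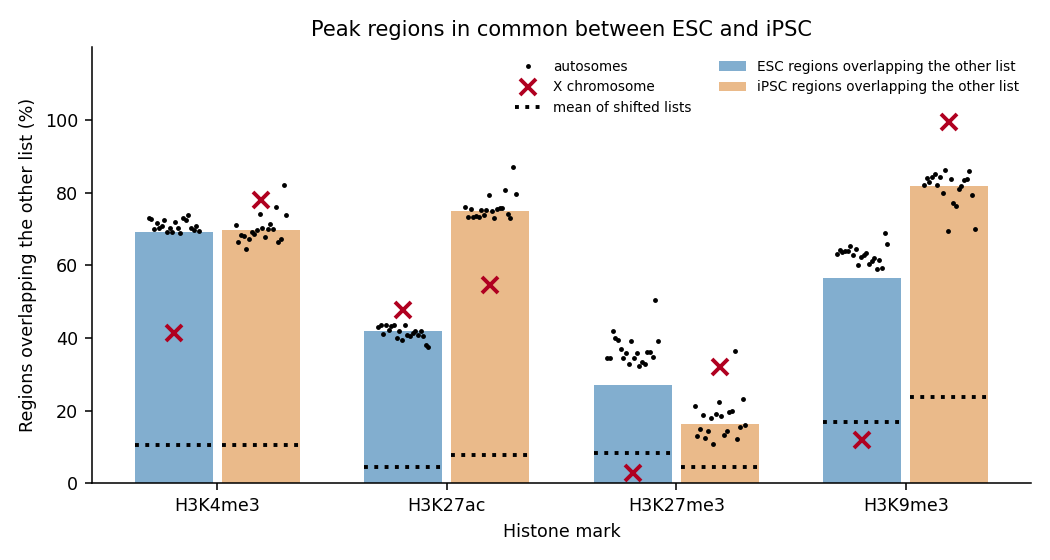
Percent of the regions of each list that overlap the other cell type's list (y axis) for each mark (x axis). Bars give all sequences, points the 20 autosomes, crosses the X chromosome and dotted lines the mean of 100 shifted lists; ESC regions of the X lie far below the autosomes for H3K4me3 (41.3%), H3K27me3 (2.71%) and H3K9me3 (12.1%).

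The ESC regions of the X stood apart from those of the autosomes for all 4 marks, with lower shares for 3 of them and a higher one for H3K27ac. The share of ESC regions in common was 71.0% ± 1.51 (SD over 20 autosomes) for H3K4me3 against 41.3% on the X, 62.9% ± 2.40 for H3K9me3 against 12.1%, and 36.8% ± 4.21 for H3K27me3 against 2.71%. For ESC H3K27ac it was 41.5% ± 1.81 on the autosomes and 47.6% on the X, and for iPSC H3K27ac 75.9% ± 3.42 and 54.7%. In the iPSC lists, 99.5% of the H3K9me3 regions of the X lay on an ESC region, against 81.1% ± 4.69 on the autosomes. These shares follow in part how much of the X the other list covers: shifted lists gave 55.2% on the X and 15.9% on the autosomes for iPSC H3K9me3, and 8.13% and 12.9% for ESC H3K9me3. For ESC H3K27me3 the 2.71% on the X lay within the range of the shifts (mean 2.30%, highest 2.98%). The ESC H3K4me3 share was 9.50 times the shifted level on the X and 7.16 times on the autosomes, so the X was not lower by this ratio. The shifted levels, 4.35% and 9.95%, differed less than the shares did, so in percentage points the X stayed lower. The autosomes differed most for iPSC H3K27me3, from 10.9% to 36.4%. Overlap also went with the strength of a peak in its own list. Of the ESC H3K4me3 peaks with the highest −log10 q, when the list was ranked into 5 equal groups, 96.8% were in common, against 46.0% of those with the lowest. The same groups gave 75.2% and 22.1% for ESC H3K27ac, 60.2% and 13.2% for ESC H3K27me3, and 85.4% and 26.9% for ESC H3K9me3. The strongest group of iPSC H3K27me3 peaks overlapped ESC peaks in 26.0%.

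Domains of H3K4me3, used in place of promoters and defined by firm H3K4me3 in either list, nearly always bore it in both cell types. They differed in the other marks. The near identity in H3K4me3 follows in part from the definition, which pooled firm peaks of both lists and counted any firm peak in a domain. Over all H3K4me3 regions, 69.3% in ESC and 69.8% in iPSC overlapped the other list. Of 25411 autosomal domains, 25180 had a firm H3K4me3 peak in both lists; 43 had one in ESC and no iPSC peak, and 46 the converse. Firm H3K27ac lay on 71.3% of them in ESC (95% Wilson interval 70.8 to 71.9) and on 55.6% in iPSC (55.0 to 56.2). Firm H3K27me3 lay on 35.4% (34.8 to 35.9) and 36.1% (35.5 to 36.7), and firm H3K9me3 on 21.1% (20.6 to 21.6) and 15.9% (15.5 to 16.4). The most frequent state was H3K4me3 with H3K27ac, at 11518 domains in ESC and 9503 in iPSC, of which 7476 were in that state in both. H3K4me3 with none of the other marks was found at 1867 domains in ESC and at 5533 in iPSC. In all, 55.0% of the domains (54.4 to 55.6) had the same state in both cell types, with a kappa of 0.419. The shorter iPSC list of H3K27ac bears on these counts: 2431 domains had firm H3K27ac in ESC and no peak in iPSC, and 227 the converse.

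Bivalent domains, a feature of developmental genes in pluripotent cells, were about equally frequent in both cell types. There were 8972 in ESC and 9130 in iPSC, against a mean of 1282 and 2821 after H3K27me3 was shifted. Of these, 6257 were bivalent in both cell types, where independent lists would give 3224. That figure leaves aside the width of the domains, with which the bivalent share rose in both lists, and so understates chance. The 6257 are 69.7% of the ESC domains (95% Wilson interval 68.8 to 70.7) and 68.5% of the iPSC domains (67.6 to 69.5). A further 1426 ESC domains had firm H3K4me3 in iPSC and had no H3K27me3 peak there, and 2211 iPSC domains had firm H3K4me3 and no H3K27me3 peak in ESC. Bivalent domains were wider than other H3K4me3 domains, with medians of 3621 and 2754 bp in ESC and 3571 and 2765 bp in iPSC. They bore firm H3K27ac less often, 48.2% against 84.1% in ESC and 42.4% against 63.4% in iPSC. Among the widest of 5 equal groups of domains, 59.9% were bivalent in each cell type, and among the narrowest 19.04% in ESC and 21.1% in iPSC. A wider domain also has more room for any peak, and firm H3K9me3 in ESC lay on 27.6% of the widest and 17.6% of the narrowest. When only H3K27me3 regions off H3K9me3 were used, 6953 domains in ESC and 6304 in iPSC were bivalent and 3850 were so in both. The count depends on the threshold and on the width limit: the stricter limits gave 5980 and 4663.

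**Figure D2:**
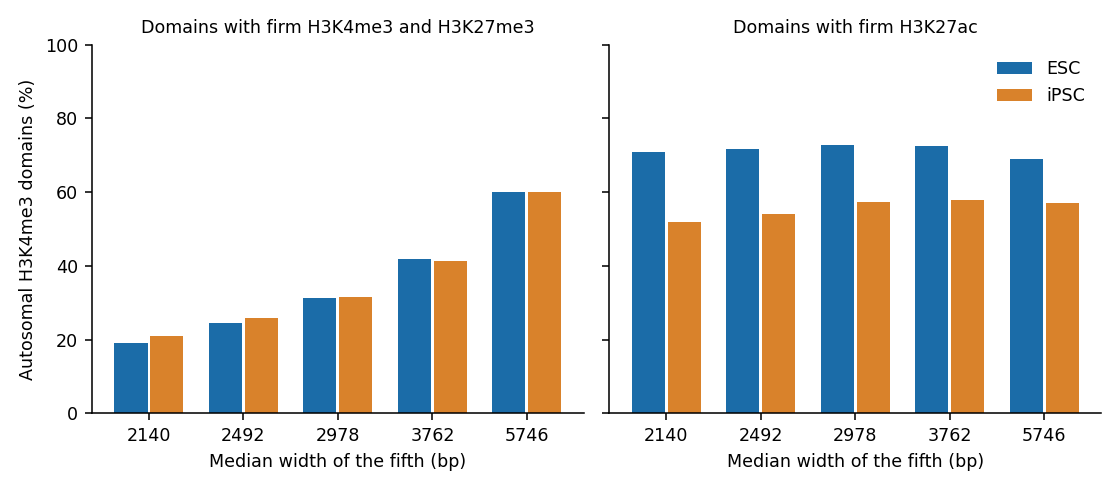
Percent of autosomal H3K4me3 domains (y axis) that were bivalent (left) or bore firm H3K27ac (right), in 5 equal groups of increasing width (x axis, median width in bp), for ESC and iPSC. The bivalent share goes from 19.04% to 59.9% in ESC and from 21.1% to 59.9% in iPSC, while the share with H3K27ac stays between 68.9% and 72.7% in ESC and between 52.0% and 57.8% in iPSC.

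The widest H3K4me3 domains were largely the same regions in both cell types and most of them overlapped H3K27me3. Of the 500 widest ESC domains, 401 (80.2%) overlapped one of the 500 widest of iPSC. Independent lists would share about 1.17, a figure that leaves the width of the domains aside and so understates chance. All 500 overlapped an iPSC peak. Their widths ranged from 10.02 to 86.6 kb in ESC and from 10.7 to 86.8 kb in iPSC. Firm H3K27me3 overlapped 88.4% of those of ESC and 89.0% of those of iPSC, firm H3K9me3 49.8% and 37.0%, and firm H3K27ac 46.6% and 39.0%. Domains this wide have room for a peak of any long list. No shifted level was computed for these overlaps or for that with iPSC H3K4me3 peaks. The widest lay at 50017236 to 50103804 of chromosome 11, an 86.6 kb domain fully covered by H3K27me3 in both cell types and free of H3K27ac peaks. Others in common lay at 114498122 to 114539251 of chromosome 11 (41.1 kb) and at 61852970 to 61892480 of chromosome 12 (39.5 kb), with H3K27me3 over 97.7% or more of their length in both lists. The next, at 104286865 to 104324472 of chromosome 2 (37.6 kb), had H3K27me3 over 55.8% of its length in ESC and 12.8% in iPSC, and H3K27ac over 13.3% and 10.1%. A 36.3 kb domain at 53254364 to 53290629 of chromosome 4 was fully covered by H3K9me3 in both cell types and by H3K27me3 in iPSC (99.4%) and not in ESC. When overlapping peaks alone were joined, 67.8% of the 500 widest ESC domains were in common.

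H3K27ac away from H3K4me3 domains was shared less often than H3K27ac at them. Within 1 kb of a domain, 60.7% of the ESC regions (95% Wilson interval 60.2 to 61.1) and 87.4% of the iPSC regions (87.0 to 87.7) overlapped the other list. Distal regions, 85.6% of the ESC list and 81.6% of the iPSC list, did so in 38.8% (38.6 to 38.9) and 72.0% (71.8 to 72.2). Distal regions also had a lower median fold, 2.89 against 3.31 in ESC and 2.85 against 3.20 in iPSC. Since overlap went with peak strength, position and strength are not separated here, and no shifted level was computed for either class. Of the 500 largest ESC clusters of distal H3K27ac, 499 held a firm distal iPSC region, but these clusters are long and 423 did so on average in shifted lists. A smaller number, 222 (44.4%), overlapped one of the 500 largest of iPSC. Independent lists would share about 3.84, a figure that leaves the length of the clusters aside and so understates chance. The largest ESC cluster lay at 34621079 to 34911647 of chromosome 3, with 75.4 kb of H3K27ac in ESC and 19.1 kb in iPSC. The next lay at 124306375 to 124543617 of chromosome 11, with 57.8 and 16.7 kb. The 1 cluster with no firm distal iPSC region lay at 69600052 to 69698524 of chromosome 20 and held 10.5 kb in ESC. Ranked by span, 32.4% of the ESC clusters were in common.

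On the X chromosome, H3K27me3 and H3K9me3 covered far more sequence in ESC than in iPSC. H3K27me3 covered 17.5% of the X in ESC and 0.801% in iPSC, against 2.26% ± 0.940 and 3.77% ± 1.63 of the autosomes (SD over 20). H3K9me3 covered 36.9% of the X in ESC and 3.35% in iPSC, against 8.68% ± 1.88 and 7.32% ± 2.51 of the autosomes. The X thus ranked first of the chromosomes for both marks in ESC and last in iPSC. It held 25612 of the ESC H3K27me3 peaks (31.8% of the list) and 2399 of those of iPSC (1.51%). H3K4me3 covered 3.95% of the X in ESC and 2.48% in iPSC, and H3K27ac 0.651% and 0.533%. Relative to the autosomes, coverage of the X was 8.43 times for H3K27me3 and 4.37 times for H3K9me3 in ESC, and 0.231 and 0.481 times in iPSC. It was 0.759 times in ESC and 0.457 times in iPSC for H3K4me3, and for H3K27ac, where this scaling turned the order, 0.165 and 0.254 times. The sex of the lines is not among the labels used here.

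**Figure D3:**
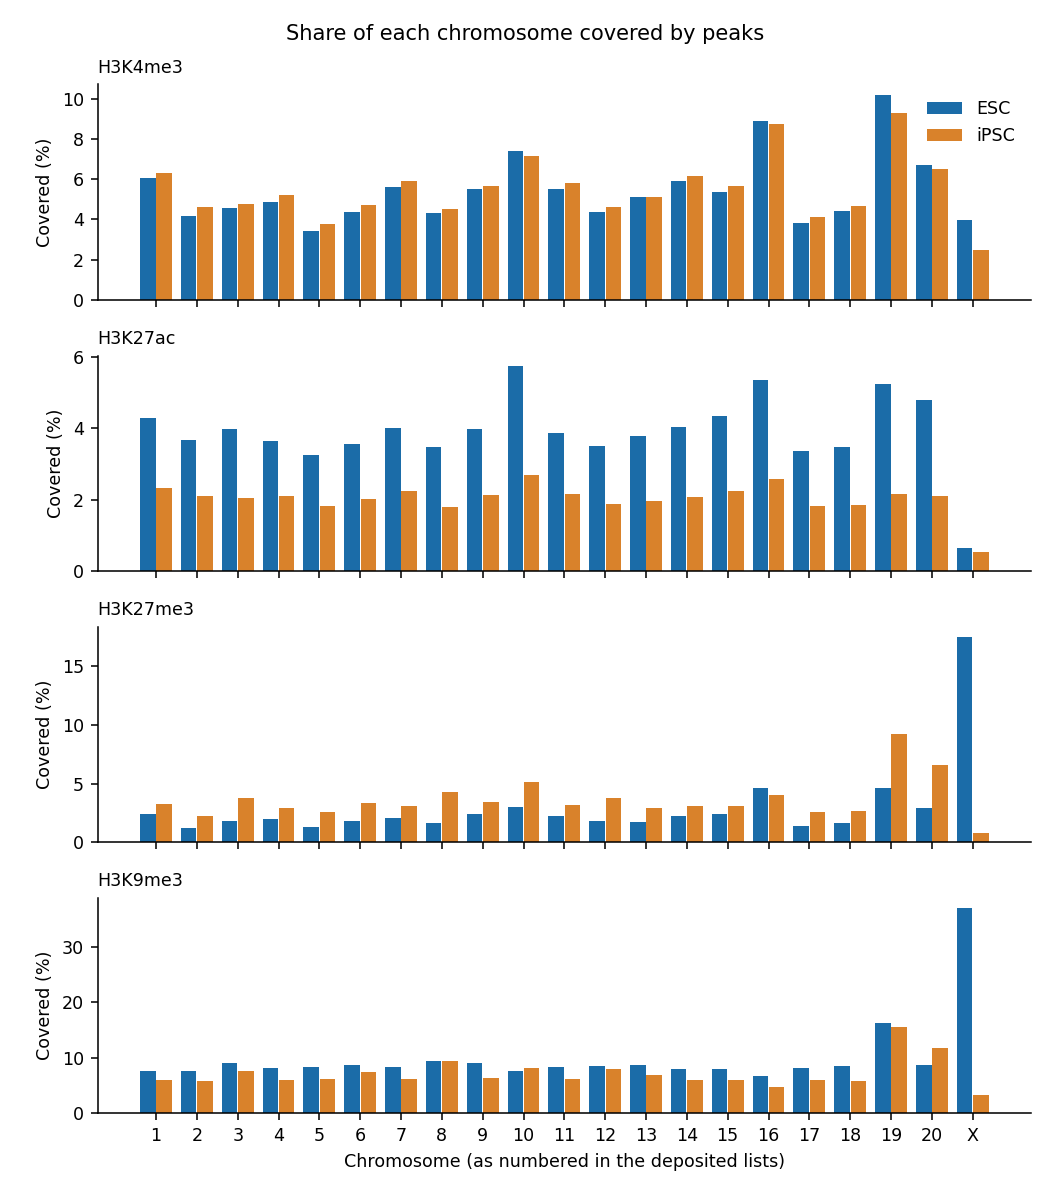
Percent of each chromosome covered by peaks (y axis) for the 20 autosomes and the X (x axis) in ESC and iPSC, with 1 panel per mark. The X stands out in ESC for H3K27me3 (17.5%) and H3K9me3 (36.9%); among the autosomes, chromosome 19 has the highest H3K9me3 coverage in both cell types (16.2% and 15.6%).

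Along the ESC X chromosome both marks were dense in different stretches at the scale of 1 Mb. In bins of 1 Mb, their coverage was inversely related (Spearman's rho −0.795, Pearson's r −0.765 over 143 bins, which are not independent). H3K27me3 exceeded H3K9me3 in 36 bins that formed 6 stretches, where they covered 51.5% ± 13.4 and 21.03% ± 6.22 (SD over bins). In the other 107 bins they covered 6.18% ± 8.25 and 42.2% ± 9.50. H3K9me3 was thus also present in the H3K27me3 bins, above its autosomal level. Within the sequence itself the marks did not avoid each other: 33.5% of the H3K27me3 base pairs of the ESC X lay in H3K9me3, 0.908 times its share of the chromosome. H3K9me3 covered less of the bins dense in H3K27me3 (21.03%), so this ratio understates the overlap within bins. A ratio to the level of each bin was not computed. The longest H3K27me3 stretch ran from 18 to 32 Mb, and others from 8 to 15, 113 to 118, 2 to 6, 119 to 123 and 82 to 84 Mb. The longest stretch of H3K9me3 ran from 32 to 82 Mb. In iPSC the same H3K27me3 bins had 0.648% ± 0.429 H3K27me3. H3K4me3 coverage of these 36 bins was 5.11% ± 2.11 in ESC and 2.05% ± 1.42 in iPSC, a ratio of 2.49, and in the other bins 3.58% ± 2.44 and 2.63% ± 2.21, a ratio of 1.36. H3K4me3 domains of the X followed the same order: 658 of 736 bore firm H3K9me3 in ESC and 101 in iPSC, and 387 and 163 bore firm H3K27me3.

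**Figure D4:**
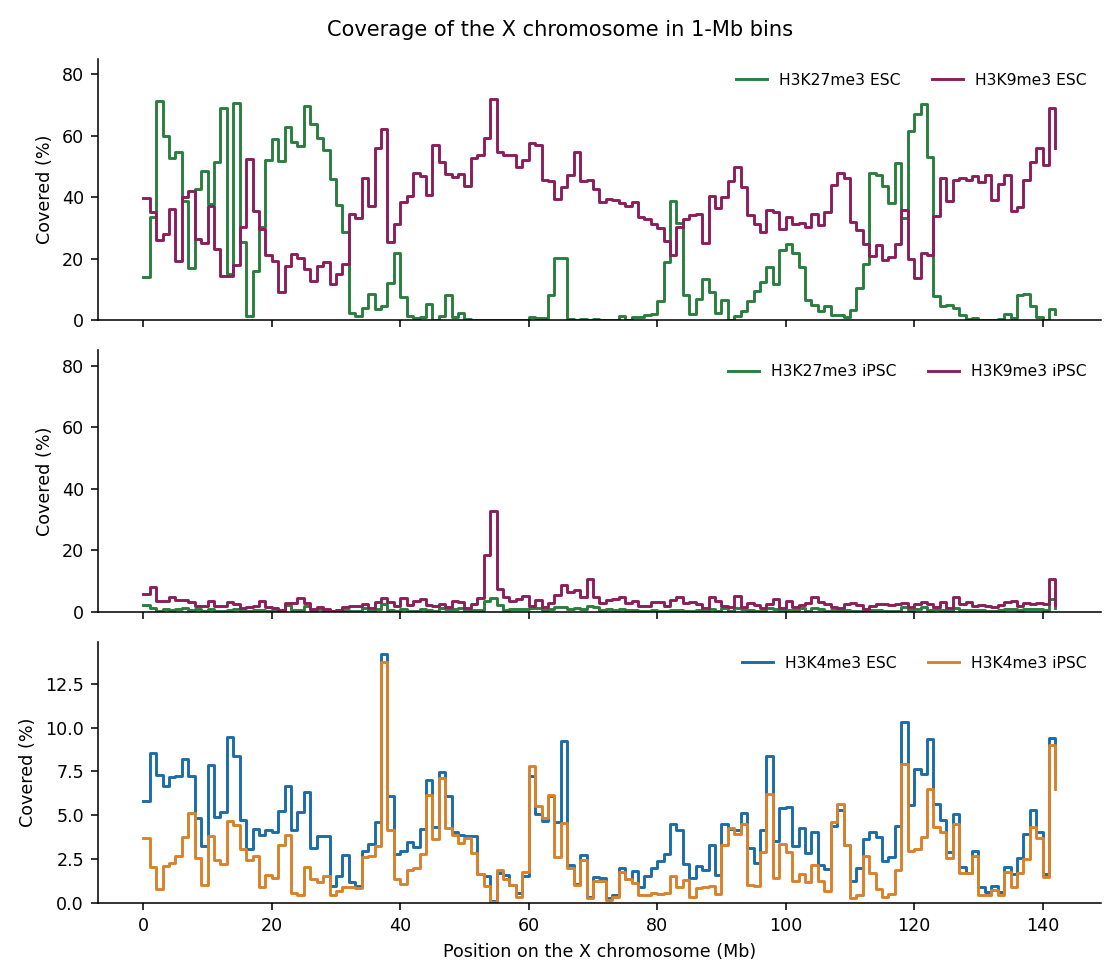
Percent of each 1-Mb bin of the X chromosome covered by peaks (y axis) by position in Mb (x axis): H3K27me3 and H3K9me3 in ESC (top) and iPSC (middle), and H3K4me3 in both (bottom). In ESC, H3K27me3 dominates from 18 to 32 Mb and from 119 to 123 Mb and H3K9me3 from 32 to 82 Mb, whereas in iPSC H3K27me3 covers 0.801% and H3K9me3 3.35% of the chromosome.

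The widest domains with no counterpart in the other list lay on the X in ESC and off it in iPSC. Of 37432 ESC H3K27me3 domains, 22204 had no iPSC peak, and 58.6% of their length was on the X. Of those at least 10 kb wide, 458 of 492 were on the X and 22 on autosomes. The widest spanned 301 kb at 22864073 to 23164748 of the X. Of 97806 iPSC H3K27me3 domains, 82005 had no ESC peak. Of those at least 10 kb wide, 4 of 1433 were on the X and 873 on autosomes. The widest spanned 129 kb at 7198501 to 7327438 of chromosome 20, where H3K9me3 covered 88.0% in iPSC and 4.26% in ESC. When the regions of the list that touched H3K9me3 of the same cell type were left out, 13472 iPSC domains had no ESC peak and 22402 ESC domains had no iPSC peak. For H3K9me3, 55250 of 176675 ESC domains and 19386 of 144637 iPSC domains were one-sided. These counts depend on the joining and the threshold: with overlapping peaks alone joined they were 58708 and 132946 for H3K27me3 and 151964 and 45487 for H3K9me3 in ESC and iPSC, and with firm peaks 12453, 54174, 40767 and 10255. The widest one-sided H3K9me3 domain of ESC spanned 161 kb at 93694097 to 93855108 of the X. That of iPSC spanned 44.7 kb at 82794502 to 82839199 of chromosome 13. The one-sided domains named here are the widest on the autosomes and the X, with unplaced scaffolds left out.

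A small part of the autosomes was covered more densely by H3K9me3 in iPSC than in ESC. Coverage was at least 20 points higher in iPSC in 29 of 2584 bins of 1 Mb, which formed 17 blocks on 9 chromosomes, and in 0 bins was it 20 points higher in ESC. Over the remaining bins the iPSC list covered less, 6.28% ± 5.03 against 8.31% ± 5.02 in ESC (SD over bins). It covered less in 2497 of these 2555 bins. A bin can be 20 points higher in ESC only where ESC covers at least 20% of it. At this ESC mean the rule largely fixed the 0 bins, which do not show that differences went 1 way. The block at 131 to 135 Mb of chromosome 8 had 76.4% H3K9me3 coverage in iPSC and 10.03% in ESC. That at 175 to 177 Mb of chromosome 3 had 79.4% and 13.8%, that at 5 to 9 Mb of chromosome 20 had 70.2% and 8.42%, and that at 88 to 90 Mb of chromosome 10 had 72.4% and 21.6%. The block with the most H3K9me3 in ESC, at 22 to 24 Mb of chromosome 19, had 75.4% in iPSC and 33.3% in ESC. H3K27ac coverage was lower in iPSC in each of the 17 blocks, and H3K4me3 coverage in 16. The exception, at 129 to 130 Mb of chromosome 8, had 3.35% H3K4me3 in iPSC and 2.72% in ESC. Of the 2555 other autosomal bins, H3K27ac coverage was lower in iPSC in 2553 and H3K4me3 coverage in 750. The H3K27ac count therefore does not set the blocks apart. H3K27ac coverage of the 29 bins was 0.461% ± 0.470 in iPSC and 2.51% ± 1.60 in ESC, a ratio of 0.184 against 0.534 in the other autosomal bins. H3K4me3 coverage was 2.26% ± 1.60 and 4.23% ± 2.13, a ratio of 0.533 against 1.05. H3K27me3 coverage was 31.3% ± 15.0 in iPSC and 2.30% ± 2.23 in ESC. In bins of 500 kb, 62 bins were 20 points higher in iPSC and 4 in ESC.

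**Figure D5:**
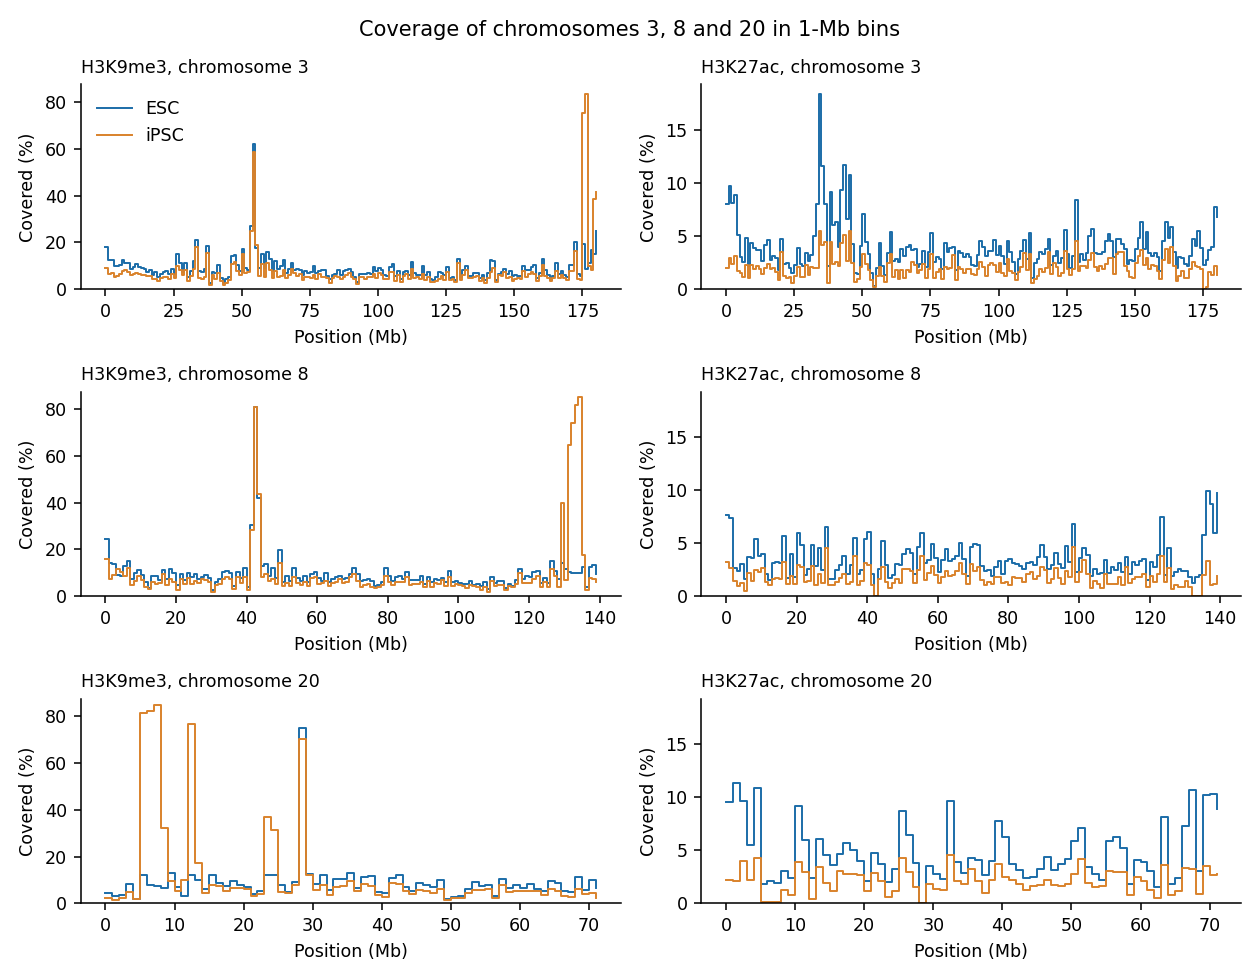
Percent of each 1-Mb bin covered by H3K9me3 (left) and H3K27ac (right) peaks (y axis) by position in Mb (x axis) on chromosomes 3, 8 and 20 in ESC and iPSC. The blocks at 175 to 177 Mb of chromosome 3, 131 to 135 Mb of chromosome 8 and 5 to 9 Mb of chromosome 20 have 79.4%, 76.4% and 70.2% H3K9me3 coverage in iPSC and 13.8%, 10.03% and 8.42% in ESC.

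The overlap of H3K27me3 with H3K9me3 and with H3K4me3 differed between the lists, most of all that with H3K9me3. On the autosomes, 46.6% of the ESC H3K4me3 regions and 32.8% of those of iPSC overlapped H3K27ac, 4.84 and 5.94 times the level of shifted lists. H3K27ac regions overlapped H3K9me3 less often than shifted lists did, 0.789 times in ESC and 0.591 times in iPSC. Of the H3K27me3 regions, 21.7% overlapped H3K9me3 in ESC (95% Wilson interval 21.4 to 22.1), 1.34 times the shifted level, and 76.7% did in iPSC (76.5 to 76.9), 6.21 times that level. H3K27me3 regions overlapped H3K4me3 in 48.1% in ESC and 27.8% in iPSC, 3.48 and 2.37 times the shifted level. They overlapped H3K27ac in 15.8% and 7.11%, close to the 14.4% and 6.80% of shifted lists. All statements on iPSC H3K27me3 above carry this overlap with H3K9me3.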

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

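Peaks on the mitochondrial sequence drew attention because they are a signal in sequence outside the chromosomes compared, which carries no histones. They number 2 to 18 per list and enter only the totals over all sequences. The peaks covered 15.8% of it in the ESC and 39.8% in the iPSC list of H3K4me3, and 3.01% and 70.7% in the lists of H3K27ac. They covered 90.9% and 93.9% in the lists of H3K27me3, and 72.9% and 92.0% in the lists of H3K9me3. The median of the authors' fold enrichment on this sequence was above that of all peaks in 4 lists and below it in the other 4. It was 4.21 against 3.13 and 4.21 against 2.77 for H3K27me3 in ESC and iPSC, 3.79 against 2.90 for iPSC H3K27ac and 4.14 against 2.65 for iPSC H3K9me3. It was 1.73 against 3.49 and 2.26 against 3.58 for H3K4me3, 2.61 against 2.95 for ESC H3K27ac and 1.94 against 2.59 for ESC H3K9me3. No explanation was tested.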

How the results depend on the processing

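The alternatives without the X, without H3K27me3 regions on H3K9me3, with other domain widths, for the blocks, and with equal numbers of peaks for the X were chosen after seeing the data. Shares were compared with the main value's Wilson interval, and counts and ratios by whether they moved over 1.5 times. No paired analysis was possible because each list is 1 per cell type and mark and carries no replicate number; for the same reason no replicate was left out in turn. Alternatives for promoters in one cell type and for zinc finger genes were not run, since the lists were not joined to genes. Unknown depth limits every count of peaks. The cause of the moves below was not tested, except that a smaller number of peaks or domains follows from a stricter setting.

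Shares in common, ESC then iPSC regions, moved as follows. With at least 50% of a region overlapped they were 64.5% and 63.7% (H3K4me3), 36.8% and 72.0% (H3K27ac), 18.3% and 13.5% (H3K27me3), and 45.5% and 74.1% (H3K9me3). With firm peaks they were 68.0% and 68.6%, 35.7% and 73.7%, 26.9% (H3K27me3, ESC), and 54.7% and 83.4%. With equal numbers of peaks they were 69.9% and 69.2%, 53.7% and 55.6%, 17.8% and 19.7%, and 66.7% and 71.2%, which turned the order of the cell types for H3K27me3. On placed chromosomes they were 69.7% (H3K4me3, ESC), 25.4% and 17.5% (H3K27me3), and 54.5% and 82.2% (H3K9me3). Without the X they were 70.7% and 69.6% (H3K4me3), 75.1% (H3K27ac, iPSC), 38.6% and 16.1% (H3K27me3), and 64.4% and 81.4% (H3K9me3). With H3K27me3 regions off H3K9me3 they were 22.7% and 51.2%. Placing regions at random gave chance levels inside the range of the shifts for H3K4me3, H3K27ac and H3K27me3, and for H3K9me3 16.6% and 22.6%.

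Bivalent domains numbered 8972 in ESC and 9130 in iPSC; the stricter limits gave 5980 and 4663, and domains of at least 3 kb 5959 and 5920. Domains in the same state were 52.9% with all peaks, 58.0% with stricter limits and 56.5% with equal numbers. The widest H3K4me3 domains in common were 67.8% with overlapping peaks joined, and distal H3K27ac clusters 32.4% by span and 34.4% joined within 5 kb. One-sided H3K27me3 domains in ESC (22204) numbered 58708 with overlapping peaks joined and 12453 with firm peaks; those in iPSC (82005) 132946, 54174, and 13472 off H3K9me3. One-sided H3K9me3 domains in ESC (55250) numbered 151964 with overlapping peaks joined; those in iPSC (19386) 45487, and 10255 with firm peaks. Bins 20 points higher in H3K9me3 were 62 in iPSC and 4 in ESC at 500 kb, and at 10 points 2 bins were higher in ESC. The coverage of the X over the autosomes kept its side of 1 and stayed within 1.5 times for each mark and cell type with firm peaks and with equal numbers. Chance levels apart, 41 alternative values stayed within these limits and 58 moved.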

Other observations

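The tests of extra DNA in the X or in the blocks, of list length, and of an antibody that binds both marks were chosen only after the results were seen; the test of H3K9me3-bearing material was chosen after the overlap of the marks was seen and before its own value was known.

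The X chromosome also differed in H3K4me3. Of 16426 ESC H3K4me3 peaks of the X, 9642 (58.7%) had no iPSC counterpart, against 28.8% of those on autosomes. The shared part was 9.50 times the shifted level on the X and 7.16 times on autosomes, so by that ratio the X was not lower. The median width of those 9642 peaks was 199 bp, close to the 191 bp of unshared autosomal peaks. They lay on H3K27ac in 6.55%, against 35.4% of the unshared autosomal peaks and 25.4% of the shared peaks of the X. ESC H3K9me3 lay under 83.2% of them, against 75.3% of the shared X peaks and 31.0% of the unshared autosomal peaks, and ESC H3K27me3 under 49.7%, against 40.4% and 4.59%. The contrasts with autosomal peaks follow in part from coverage in ESC. On the X and the autosomes it was 36.9% and 8.46% for H3K9me3, 17.5% and 2.08% for H3K27me3, and 0.651% and 3.95% for H3K27ac. In bins of 1 Mb, H3K27me3 coverage of the X in ESC and iPSC showed little relation (Spearman's rho −0.0737 over 143 bins, which are not independent), and that of H3K27ac a close one (0.875).

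Unplaced scaffolds, 123 Mb in 21521 sequences, were rich in H3K9me3 in both cell types, at 35.3% coverage in ESC and 32.4% in iPSC. H3K27me3 covered 2.19% of them in ESC and 15.3% in iPSC. Of that H3K27me3 sequence, 50.2% lay in H3K9me3 in ESC and 94.7% in iPSC. Chromosome 19 as numbered in the lists had the highest H3K9me3 coverage of the autosomes in both cell types, 16.2% and 15.6%, and in iPSC also the highest H3K27me3 coverage, 9.24% against 4.61% in ESC.

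H3K27me3 and H3K9me3 covered far more of the X in the ESC lists. For extra X DNA in the ESC libraries relative to their input, the prediction was that both marks would rise together along the chromosome. Their coverage was inversely related (rho −0.795), which cannot decide, since an even gain over the X leaves the order of its bins unchanged. Such a gain would raise coverage in all bins. H3K27me3 covered 1.52% of the 36 bins richest in H3K9me3, against 2.08% of the autosomes, which argues against it for H3K27me3 and leaves H3K9me3 undecided. In iPSC the X ranked last of the chromosomes for all 4 marks. In ESC it also ranked last for H3K27ac, and 19th of 21 for H3K4me3. Relative to the autosomes, its H3K27ac coverage was higher in iPSC than in ESC (0.254 against 0.165 times). Its H3K4me3 coverage was lower (0.457 against 0.759 times). Too little X DNA in the iPSC libraries was not tested. List length is argued against for H3K9me3, whose ESC list is the longer: with the same number of peaks, the coverage of the X over the autosomes in ESC was 9.04 times that in iPSC. For H3K27me3 the ESC list is the shorter one. A difference between the cell types or between the lines stays open and was not tested, since line and cell type are confounded and the sex of the lines is not among the labels used here.

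Megabase blocks of H3K9me3 appeared on autosomes in the iPSC list. More DNA of the blocks in the iPSC libraries than in their input would raise every mark there, and H3K4me3 coverage, iPSC over ESC, was instead 0.509 times that of the other autosomal bins. A longer iPSC list cannot account for the blocks, since that list was the shorter one, with 0.721 times the peaks of the ESC list. A difference between the cell types or between the lines stays open and was not tested, and whether 1 line or both carry the blocks is open. Of the 17 blocks, 5 lay within 5 Mb of a chromosome end.

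H3K27me3 lay on H3K9me3 in the iPSC lists. H3K9me3-bearing material in the iPSC H3K27me3 libraries is a candidate explanation: outside the blocks, H3K27me3 covered 40.3% of the length of the strongest and 16.6% of the weakest of 5 equal groups of autosomal iPSC H3K9me3 peaks by fold, a ratio of 2.42, against 0.423 in ESC. The test of an antibody that binds both marks in every library used the 36 X bins richest in ESC H3K9me3. ESC H3K27me3 coverage there was 0.0862 times the mean of the X. That ratio cannot decide, since bins dense in H3K27me3 raise the mean and the inverse relation along the X was already known. The coverage itself, 1.52% against 2.08% of the autosomes, argues against binding that would mark most H3K9me3 sequence. Weaker binding stays open, since ESC H3K27me3 regions of the autosomes overlapped H3K9me3 1.34 times as often as shifted lists did. A true presence of both marks on the same sequence in iPSC could also give the relation to H3K9me3 strength and stays open. Part of the iPSC H3K27me3 list, including that in the blocks, is therefore uncertain.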
